A study of Homo sapiens with 6 samples.

How the data were processed

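The study profiled MCF-7 cells, an estrogen receptor positive breast cancer cell line, by droplet single-cell RNA sequencing after treatment with single drugs and their combinations. Per the labels, cells grown in multi-well plates were given vehicle (DMSO), palbociclib (a CDK4 and CDK6 inhibitor), giredestrant (a degrader and antagonist of the estrogen receptor), inavolisib (a PI3K alpha inhibitor), each pair of drugs or all 3 drugs, at 200 nM, either 24 or 96 h before collection. Cells were hashed with lipid-modified oligonucleotides and pooled, giving 3 gene expression libraries and 3 hashtag oligonucleotide libraries.

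The deposited matrix holds raw UMI counts (whole numbers, not normalised) for 36601 genes in 26602 cells, made by the authors with Cell Ranger on GRCh38; neither version is given. The lowest total of a cell was 500 UMIs. The deposited cell table holds text labels for the drug, the treatment time and the cell line of each cell. How hashtags were assigned and whether doublets were removed is not stated, and no doublet caller was run here. A condition was given for 11794 cells and none for 14808 cells (55.7%), which entered no comparison. In the table, giredestrant and inavolisib appear as development codes, which were read as these drugs from their established development names. All cells carry the line name MCF-7 and a single sample name, so the ESR1-mutant line named in the series could not be told apart and no cell could be assigned to a library. Comparisons between lines, fits with library as a term and fits without each library were therefore not run. The tissue field of the labels says colon, whereas the cell table says breast.

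UMI counts were summed over the cells of each of the 16 conditions (8 treatments at 2 times). Each condition is 1 value without a replicate, and the number of wells behind it is not stated. All 16 sums were fitted together in edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood fit) under R 4.3.3, with terms for time, each drug, each drug pair and each drug by time, time being centred. The model has 11 terms and leaves 5 residual degrees of freedom. These come from the higher-order interactions (drug pair by time and all 3 drugs), so the tests assume that those are small. Where they are not, they widen the error and can also shift the coefficients, which are fitted over all drug backgrounds. A coefficient can then differ from the plain difference between single cultures. Of 27652 genes with a count, 14100 were tested. The biological coefficient of variation was 0.0825. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Coefficients of single drugs compare drug with vehicle, averaged over both times; pair terms give the departure of a combination from the sum of the single log2 effects; drug by time terms give the effect at 96 h minus that at 24 h. Contrasts for a drug added to another, and for all 3 drugs against vehicle, are sums of these terms and were added after seeing the data. Log2 fold changes are given with a standard error (SE). It was worked back from the test, as the absolute log2 fold change over the square root of the F statistic. A pair, below, is a pair of conditions that differ only in 1 drug or only in time; each factor has 8.

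The genes named follow a rule: for each single drug and for time, the 8 largest rises and falls among called genes with a mean of at least 10 CPM (counts scaled to effective library size, as edgeR reports them) that moved the same way in all 8 pairs (relaxed to 6 pairs where fewer than 8 passed, as for palbociclib and time); for interactions and sums of terms, the 3 smallest p in each direction; ESR1, TFF1, GREB1, PGR, PDZK1, CCND1, E2F1, MKI67, CDKN1A and IRS2 in any case; and the members of each list with the largest change. For single drugs and time the ranking left out mitochondrially encoded, ribosomal protein, antisense and clone-named genes. Statements on the largest rises and falls hold within this rule. Of 173 named genes, 172 were placed by Ensembl identifier in GENCODE 29 (GRCh38), which may differ from the annotation the authors used. A total of 22 gene lists was tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists within a contrast; the same test with the correlation estimated per list stands beside it. The design, lists, rule for names and alternative settings were fixed before the data were examined, unless stated.

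A cell was scored as cycling if it had at least 1 UMI of MKI67, TOP2A, CCNB1, CDK1 or TPX2 after thinning to 1000 UMIs; cells below 1000 UMIs were left out. Shares carry 95% Wilson intervals and CPM values 95% exact Poisson intervals, which cover counting error only. Drugs were compared over their 8 pairs with an exact two-sided sign-flip permutation test, whose smallest possible p is 0.00781, adjusted over the 3 drugs. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5 was used.

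Alternatives were DESeq2 1.42.0 in place of edgeR, no filter on low counts, only cells with at least 2000 UMIs and at most 15% mitochondrial UMIs, an equal 430 cells per condition, models with fewer or more interaction terms and other definitions of a cycling cell. Leaving out each condition in turn, omitting the scaling factors and scoring only cells with at most 10% mitochondrial UMIs were chosen after seeing the data. The pipeline was tested on simulated counts of the same design, with 100 genes changed per comparison by a log2 change of 1 and 100 by 0.5. At a log2 change of 1 it recovered 61 of 100 genes for giredestrant, 68 for palbociclib, 69 for inavolisib, 58 for time, 51 for giredestrant by time and 48 for inavolisib by time. At a log2 change of 0.5 it recovered 26, 21, 33, 18, 12 and 16, respectively, with 0 calls in the wrong direction. False calls among unchanged genes numbered 10, 4, 9, 6, 5 and 5 in the same order. For the giredestrant + inavolisib pair term it recovered 59 genes at a log2 change of 1 and 10 at 0.5, with 6 false calls. The simulation thus misses many changes of these sizes, and low counts of calls are read with that in mind. Except for palbociclib, false calls were also a larger share of all calls than the adjusted p threshold. The calls can therefore not be read as conservative.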

Results

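Single-cell transcriptomes of MCF-7 breast cancer cells were compared across 8 treatments at 24 and 96 h, with 1 culture condition for each of the 16 combinations and no replicates. Conditions held from 430 cells (palbociclib + giredestrant, 96 h) to 926 cells (vehicle, 96 h). Their summed depth ranged from 2269292 UMIs (all 3 drugs, 96 h) to 6221626 UMIs (vehicle, 96 h), and the median cell held from 3993 to 6727.5 UMIs. Luminal breast epithelium markers summed to 15111 CPM, led by KRT18 (5946 CPM) and KRT8 (3615 CPM), both keratins of simple epithelia. Colon epithelium markers, checked because the tissue field names colon, summed to 2.88 CPM, fibroblast markers to 1.68 CPM, blood cell markers to 3.68 CPM, and basal and mesenchymal markers to 85.6 CPM. The mean mitochondrial share of UMIs per cell lay between 6.45% and 9.84% in the conditions at 24 h and between 2.72% and 7.99% at 96 h.

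The first comparison asked what blocking the estrogen receptor did. Giredestrant lowered most of the classical estrogen-induced genes. AREG, which encodes the EGFR ligand amphiregulin (ENSG00000109321, GRCh38 chromosome 4, 74445134 to 74455009, plus strand), fell by 3.88 on the log2 scale (SE 0.22, adjusted p = 1.3e-07), from 112 to 5.2 CPM at 24 h and from 103 to 9.4 CPM at 96 h. The progesterone receptor gene PGR (ENSG00000082175, chromosome 11, 101029624 to 101130524, minus strand) fell by 2.92 (SE 0.14, adjusted p = 1.9e-15), from 110 to 19.4 CPM at 24 h and from 83.2 to 9.03 CPM at 96 h. GREB1, an estrogen receptor cofactor, changed by -2.91 (SE 0.18), TFF1, a secreted trefoil peptide, by -2.61 (SE 0.17), and PDZK1, a scaffold protein, by -2.73 (SE 0.27). All of these except PDZK1 were lower in 8 of 8 pairs, and PDZK1 in 6 of 8. ESR1 itself, the gene of the drug's target, had a log2 fold change of 0.17 (SE 0.11, adjusted p = 0.36).

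**Figure D1:**
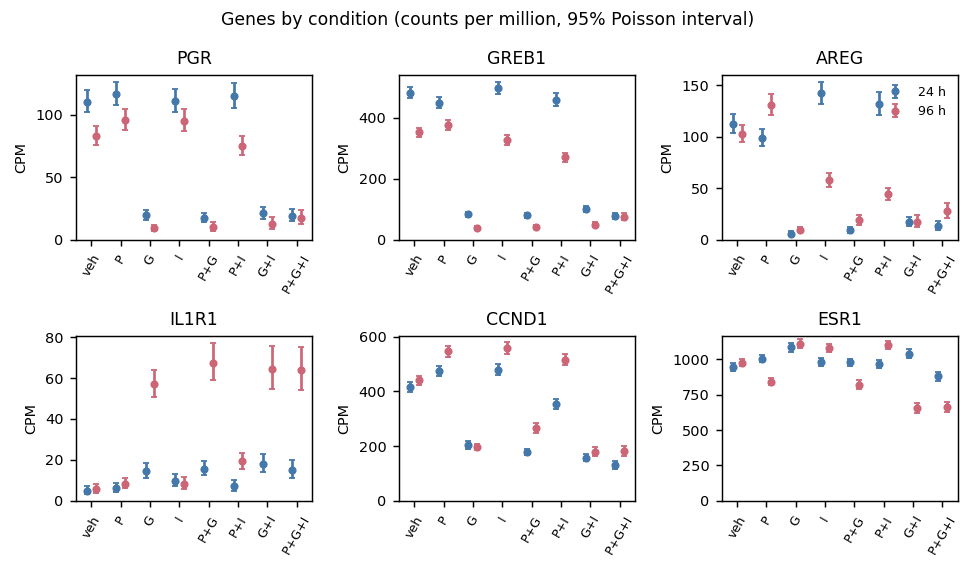
CPM (vertical axis, from 0) of PGR, GREB1, AREG, IL1R1, CCND1 and ESR1 in the 8 treatments (horizontal axis) at 24 h (blue) and 96 h (red), with 95% Poisson intervals for counting error. PGR lay between 9.03 and 20.9 CPM in the conditions with giredestrant and between 75.3 and 117 CPM in those without it.

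Of 31 measured estrogen-induced genes, 27 fell with giredestrant over all genes tested, 30 when adjusted over the list alone, and the list median was -1.79 (adjusted p = 3.9e-32, and 0.016 with an estimated correlation). MYBL1, a transcription factor of the MYB family, changed by -2.81 (SE 0.20). Of 10 estrogen-repressed genes, 5 rose (7 adjusted over the list alone). Their median was 0.86 with an adjusted p of 4.5e-05, or adjusted p = 0.063 with an estimated correlation. They included the interleukin-1 receptor gene IL1R1 (ENSG00000115594, chromosome 2, 102064544 to 102179874, plus strand; log2 fold change 2.58, SE 0.19, adjusted p = 1.9e-11), PSCA (2.93, SE 0.37), a surface antigen, and BIK (1.79, SE 0.25), a pro-apoptotic BCL2 family member. BMF did not pass, with 1.16 (SE 0.41, adjusted p = 0.058). The other largest rises were CLEC3A (2.54, SE 0.20), PMP22 (2.05, SE 0.19), a myelin protein, NPAS3 (1.94, SE 0.35), APOD (1.83, SE 0.18), a lipid carrier, PRKG1 (1.81, SE 0.16), the cGMP-dependent kinase, and LUZP2 (1.79, SE 0.18). The other largest falls were ATRNL1 (-3.16, SE 0.35), SYTL5 (-3.16, SE 0.19), CALCR (-3.13, SE 0.22), the calcitonin receptor, MGP (-3.12, SE 0.60), a calcification inhibitor, and NPY1R (-3.10, SE 0.22), a neuropeptide Y receptor.

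Giredestrant also lowered CCND1 and MYC, and a minority of the cell cycle genes were called as lower. Most of the others had negative estimates without passing, as the upper quartile over genes was -0.51 for G1/S and -0.58 for G2/M genes. CCND1, which encodes cyclin D1, changed by -1.16 (SE 0.10, adjusted p = 2.5e-10) and MYC by -1.56 (SE 0.20, adjusted p = 1.2e-06), each lower in 8 of 8 pairs, and E2F1, the S-phase transcription factor, by -1.50 (SE 0.41, adjusted p = 0.013). Among 30 G1/S and DNA replication genes 8 fell, 12 adjusted over the list alone, with a median of -0.79 (adjusted p = 0.54 with an estimated correlation, 1.1e-08 without). ORC1, an origin-binding protein, changed by -2.29 (SE 0.74), while RRM2 (-1.35, SE 0.54) and MCM10 (-1.47, SE 0.84) did not pass. Among 30 G2/M and mitosis genes 10 fell, 11 adjusted over the list alone, with a median of -0.72 (adjusted p = 0.55 with an estimated correlation, 6.1e-09 without). They included NDC80 (-1.20, SE 0.29) and NUF2 (-1.08, SE 0.25) of the kinetochore and HMMR (-1.13, SE 0.18). MKI67 had -0.54 (SE 0.51, adjusted p = 0.60) and CDKN1A, the p21 gene, 0.34 (SE 0.30, adjusted p = 0.56).

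Several metabolic and signalling lists moved with giredestrant by the preset test only. ATF4 and amino acid genes fell in 14 of 25 cases (18 lower and 1 higher adjusted over the list alone, median -0.77, adjusted p = 0.49 with an estimated correlation). Among them were SLC7A11, the cystine transporter (-2.42, SE 0.61), CHAC1, a glutathione-degrading enzyme (-2.23, SE 0.47), and PHGDH, which opens serine synthesis (-2.11, SE 0.36). MYC and ribosome biogenesis genes fell in 9 of 22 cases (14 adjusted over the list alone, median -0.36, adjusted p = 0.063 with an estimated correlation). FOXO and PI3K feedback genes split, with 6 of 24 higher and 3 lower (8 and 3 adjusted over the list alone, median 0.37, adjusted p = 0.18 with an estimated correlation). TP53INP1 rose by 0.97 (SE 0.14) and IGF1R, the IGF receptor, changed by -1.20 (SE 0.11), while IRS2 had -0.30 (SE 0.20, adjusted p = 0.38). Lysosome and autophagy genes had 6 of 18 higher and 1 lower (9 and 2 adjusted over the list alone, median 0.28, adjusted p = 0.54 with an estimated correlation). NEU1 (0.76, SE 0.13) and SQSTM1 (0.62, SE 0.11) were higher and GLA (-1.30, SE 0.16) was lower. Interferon and antigen presentation genes had 5 of 24 higher, 5 also adjusted over the list alone (median 0.33, adjusted p = 0.55 with an estimated correlation). Mitochondrially encoded genes had 4 of 13 lower, 7 adjusted over the list alone (median -0.24, adjusted p = 0.67 with an estimated correlation), such as MT-ND2 (-0.36, SE 0.10).

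In all, giredestrant changed 2042 of 14100 genes (974 higher, 1068 lower) in edgeR. Without scaling factors, which moved the median of all genes to 0.0958, the split was 1386 higher and 725 lower. DESeq2 called 864 genes. The count fell to 1135 without giredestrant at 24 h, to 1233 without giredestrant at 96 h and to 1234 without vehicle at 24 h.

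Palbociclib changed few genes. HIST2H2AC, a histone gene, changed by -0.75 (SE 0.13, adjusted p = 0.015) and CKS1B, a CDK subunit, by -0.62 (SE 0.11, adjusted p = 0.015), both lower in 8 of 8 pairs. DUT, which keeps uracil out of DNA, changed by -0.66 (SE 0.11, adjusted p = 0.013; lower in 7 of 8 pairs). Higher were CCDC83 (0.97, SE 0.20), ITPR1, a calcium channel of the endoplasmic reticulum (0.71, SE 0.15), and the protease gene PRSS23 (0.51, SE 0.11), each with an adjusted p of 0.048. Each of these was higher in at least 6 of 8 pairs, but none in all 8. None of the 30 G1/S and DNA replication genes passed, but their median was -0.61 (adjusted p = 2.3e-18, and 0.48 with an estimated correlation), as in CDC45 (-1.68, SE 0.48) and CDT1 (-1.19, SE 0.28). None of the 30 G2/M and mitosis genes passed over all genes and 1 did adjusted over the list alone, with a median of -0.49 (adjusted p = 1.2e-11, and 0.56 with an estimated correlation), as in AURKB (-1.08, SE 0.27).

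The G1/S median of the palbociclib pairs was -1.02 in otherwise untreated cells at 24 h and 0.10 at 96 h, against -1.18 on top of inavolisib, -0.88 on top of giredestrant and -0.05 on top of both at 96 h. These medians of single pairs were not tested. ATF4 and amino acid genes had 1 of 25 lower (6 adjusted over the list alone, median -0.39, adjusted p = 0.49 with an estimated correlation). The p53 target genes had a median of -0.19 with 0 of 21 called and 2 lower adjusted over the list alone (adjusted p = 0.68 with an estimated correlation), and MYC and ribosome biogenesis genes one of -0.11 with 0 of 22 called by either adjustment (adjusted p = 0.48 with an estimated correlation). PGR (0.09, SE 0.11), GREB1 (-0.05, SE 0.16), TFF1 (0.08, SE 0.17), CCND1 (0.19, SE 0.10), E2F1 (-0.75, SE 0.37) and MKI67 (-0.54, SE 0.51) did not pass. In all 12 genes passed (7 higher, 5 lower) in edgeR, with 995 at an unadjusted p below 0.05 where 705 would be due to chance. DESeq2 called 0, and so did edgeR without scaling factors. Over fits lacking 1 condition each, the count ran from 2 (without palbociclib at 24 h) to 190 (without palbociclib at 96 h), with 171 without vehicle at 96 h.

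Inavolisib raised genes that FOXO factors and PI3K feedback are known to control. Of 24 such genes 5 rose, 9 adjusted over the list alone, with a median of 0.37 (adjusted p = 4e-10, and 0.017 with an estimated correlation). PIK3IP1, a PI3K inhibitor protein, rose by 1.04 (SE 0.26, adjusted p = 0.042), TXNIP, a brake on glucose uptake, by 0.64 (SE 0.12, adjusted p = 0.0059), and MXI1, a MYC antagonist, by 0.63 (SE 0.15, adjusted p = 0.027), each in 8 of 8 pairs. IRS2 was higher in 8 of 8 pairs as well (0.51, SE 0.19) without passing (adjusted p = 0.28), as was ERBB3 (0.39, SE 0.10, adjusted p = 0.058). The other largest rises were N4BP2L1 (1.12, SE 0.21), ABHD2 (0.84, SE 0.15), YPEL3 (ENSG00000090238, chromosome 16, 30092314 to 30096915, minus strand; 0.84, SE 0.10, adjusted p = 5.5e-06), NXNL2 (0.71, SE 0.15), FXYD3, a regulator of the sodium pump (0.67, SE 0.11), and GSTM3, a glutathione transferase (0.62, SE 0.10).

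Falls with inavolisib were ranked among called genes of at least 10 CPM that were lower in 8 of 8 pairs, mitochondrially encoded genes left out. The largest of these were the retinoic acid binding proteins CRABP1 (-0.99, SE 0.17) and CRABP2 (-0.44, SE 0.09), TSEN15 of the tRNA splicing complex (-0.72, SE 0.13) and CRELD2, an endoplasmic reticulum stress protein (-0.69, SE 0.18). With them were SCD, the stearoyl-CoA desaturase (-0.61, SE 0.14), CLSTN2 (-0.53, SE 0.11), MED12L (-0.48, SE 0.12) and ATP5MC1, a subunit of the ATP synthase (-0.43, SE 0.09). Mitochondrially encoded genes fell in 8 of 13 cases (12 adjusted over the list alone, median -0.43, adjusted p = 0.28 with an estimated correlation), such as MT-CO3 (-0.54, SE 0.11) and MT-ATP8 (-0.56, SE 0.11). The mean mitochondrial share per cell was 4.64% with inavolisib and 7.65% with vehicle at 96 h, and 9.07% against 8.80% at 24 h. ATF4 and amino acid genes fell in 6 of 25 cases (14 adjusted over the list alone, with 1 higher, median -0.56, adjusted p = 0.28 with an estimated correlation), such as CHAC1 (-2.46, SE 0.49), which had 6 UMIs with inavolisib alone at 24 h and 3 at 96 h. MAPK early-response genes had 2 of 18 higher (6 adjusted over the list alone, median 0.46, adjusted p = 0.28 with an estimated correlation). Among estrogen-repressed genes IL1R1 rose (0.92, SE 0.21), 1 of 10 called and 2 adjusted over the list alone (adjusted p of the list 0.042, and 0.28 with an estimated correlation).

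Further lists reached the preset threshold with inavolisib at small medians, the last value being the adjusted p with an estimated correlation. They were G1/S genes (median -0.10, 0 of 30 called, 0.66) and G2/M genes (median -0.10, 0 of 30 called, 0.66). Cholesterol and fatty acid synthesis genes (median -0.17, SCD as 1 of 28 lower, 0.56) and unfolded protein response genes (median -0.13, CRELD2 as 1 of 14 lower, 2 adjusted over the list alone, 0.46) were the others. TFF1 had -0.69 (SE 0.17, adjusted p = 0.11) and PGR 0.05 (SE 0.12). In all 139 genes changed (81 higher, 58 lower; 48 and 54 without scaling factors). DESeq2 called 48. The count ranged, with any 1 condition omitted, from 39 (without inavolisib at 24 h) to 342 (without vehicle at 96 h), with 43 without inavolisib at 96 h, 48 without vehicle at 24 h and 257 without palbociclib at 96 h.

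**Figure D2:**
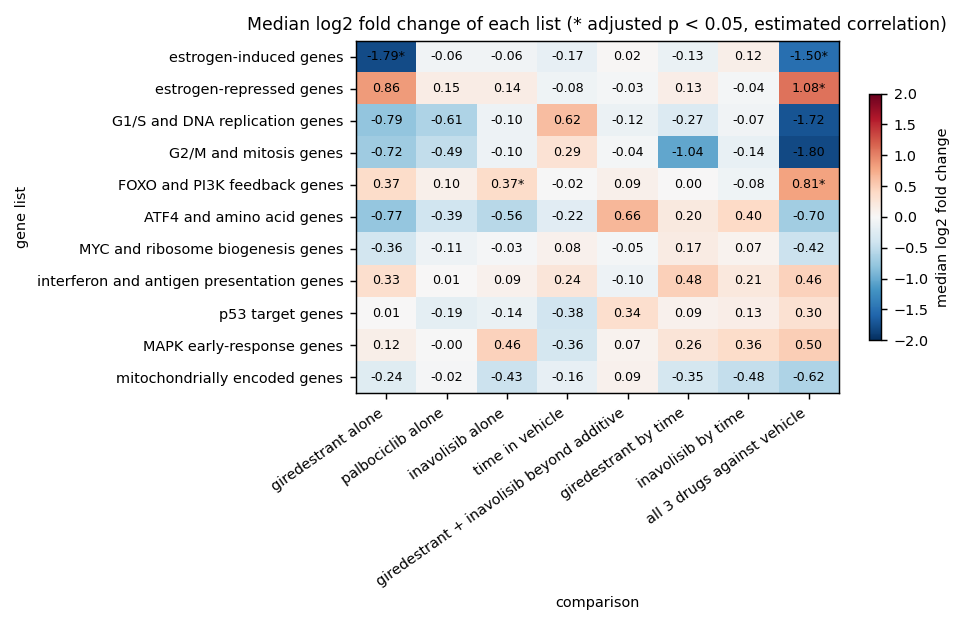
Median log2 fold change (colour and printed value) of 11 gene lists (rows) in 8 comparisons (columns); a star marks an adjusted p below 0.05 with an estimated correlation. Estrogen-induced genes stood at -1.79 with giredestrant and FOXO and PI3K feedback genes at 0.37 with inavolisib.

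Time since treatment, 96 h against 24 h with vehicle, changed 18 genes (3 higher, 15 lower). This term is fitted over all drug backgrounds. It can differ from the plain difference between the vehicle cultures, since the model has no drug pair by time terms. The metallothionein genes MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196, plus strand; 1.53, SE 0.13, adjusted p = 2.1e-08) and MT2A (1.42, SE 0.13, adjusted p = 6.9e-07) rose in 8 of 8 pairs. Lower were FHL2 (-2.11, SE 0.25), the immediate-early transcription factors EGR1 (-1.72, SE 0.18) and IER2 (-0.68, SE 0.12), the amino acid transporter SLC7A5 (-0.94, SE 0.18), the p53 regulator MDM2 (-0.64, SE 0.12), the Notch target HES1 (-0.60, SE 0.11) and STARD13 (-0.55, SE 0.12). Each was lower in at least 6 of 8 pairs. Of the 9 called falls that the rule for names could rank, 2 were lower in all 8. Of 18 MAPK early-response genes 3 fell, 7 adjusted over the list alone (median -0.36, adjusted p = 0.22 with an estimated correlation). Further lists passed with the preset correlation only, the last value of each being its adjusted p with an estimated correlation. Lower were p53 targets (median -0.38, 1 of 21 lower and 2 adjusted over the list alone, 0.36) and estrogen-induced genes (median -0.17, 1 of 31 lower, 7 lower and 1 higher adjusted over the list alone, 0.22). Also lower were ATF4 and amino acid genes (median -0.22, 1 of 25 lower, 0.63) and mitochondrially encoded genes (median -0.16, 0 of 13 and 4 lower adjusted over the list alone, 0.63). Higher were G1/S genes (median 0.62, 0 of 30 called, 0.63), G2/M genes (median 0.29, 0 of 30 called, 0.81) and interferon genes (median 0.24, 0 of 24 called, 0.63). The share of cycling cells in vehicle did not rise, at 14.7% at 24 h and 13.3% at 96 h. The cell cycle medians of this term therefore need not hold for the vehicle cultures themselves. DESeq2 called 7 genes. Leaving out 1 condition at a time moved the count from 5 (without giredestrant at either time) to 265 (without vehicle at 96 h), with 38 without palbociclib at 96 h.

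The share of cycling cells was compared next. Vehicle cultures had 14.7% cycling cells (95% interval 12.5 to 17.3) at 24 h and 13.3% (11.2 to 15.7) at 96 h. At 24 h the share was 6.82% with palbociclib (5.32 to 8.72), 11% with giredestrant (8.94 to 13.6), 11.2% with inavolisib (9.28 to 13.5) and 7.53% with all 3 drugs (5.64 to 9.99). The pairs at 24 h stood at 7.49% (palbociclib + giredestrant), 7% (palbociclib + inavolisib) and 9.31% (giredestrant + inavolisib). At 96 h the share was 15.6% with palbociclib alone (13.1 to 18.5), 9.86% with giredestrant alone (7.91 to 12.2) and 16.8% with inavolisib alone (14.3 to 19.6). In the combinations at 96 h it was 5.08% with palbociclib + giredestrant (3.35 to 7.65), 7.81% with palbociclib + inavolisib (6.14 to 9.88), 7.67% with giredestrant + inavolisib (5.52 to 10.6) and 5.32% with all 3 drugs (3.57 to 7.86). Over the 8 pairs palbociclib went with a mean difference of -3.91 percentage points (SD 3.55, n = 8; lower in 7 of 8; exact p = 0.0234, adjusted p = 0.0469). Giredestrant went with -3.75 (SD 4.10, n = 8; lower in 6 of 8; exact p = 0.0312, adjusted p = 0.0469), and inavolisib with -1.41 (SD 3.32, n = 8; lower in 4 of 8; exact p = 0.312). With thinning to 2000 UMIs the differences were -3.85 for giredestrant and -4.37 for palbociclib, with list-score phases -9.07 and -5.55, and in cells with at most 10% mitochondrial UMIs -3.87 and -3.51. None of these passed after adjustment. Without thinning giredestrant passed (-7.68, adjusted p = 0.0234) and palbociclib did not (-4.04, adjusted p = 0.141). Inavolisib passed there as well (-5.36, lower in 7 of 8, adjusted p = 0.0352). It did not pass at 2000 UMIs (-2.96), with list-score phases (-1.96) or in cells with at most 10% mitochondrial UMIs (-1.55). The level itself depends on the definition. Vehicle at 24 h had 34.1% without thinning, 21.0% at 2000 UMIs and 50.6% with list-score phases, so differences under unlike definitions are not on a common scale. The data hold no cell type that lacks these genes, so the share of cells with a UMI from free RNA is unknown.

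**Figure D3:**
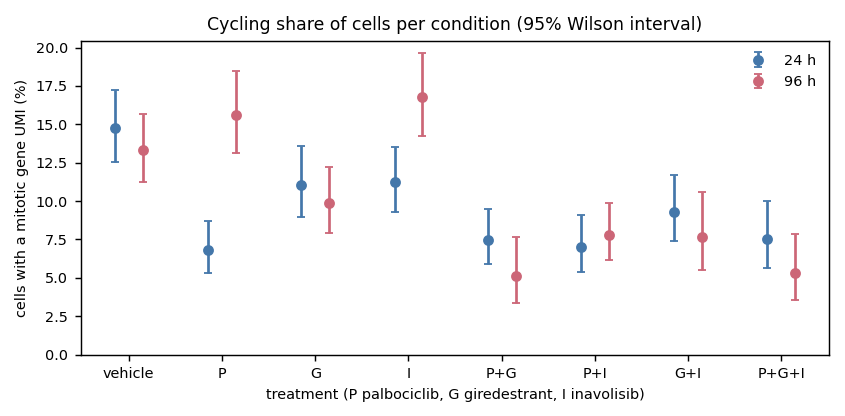
Percentage of cells with a UMI of a mitotic gene after thinning (vertical axis, from 0) by treatment (horizontal axis) at 24 h (blue) and 96 h (red), with 95% Wilson intervals. Palbociclib alone stood at 6.82% at 24 h and at 15.6% at 96 h, where its combination with giredestrant stood at 5.08%.

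Combinations were then set against the sum of the single effects, in pair terms averaged over both times. Few genes were called, but these terms can miss a departure at a single time. At 96 h the G2/M medians against vehicle were 0.03 with palbociclib, -0.65 with giredestrant and 0.24 with inavolisib. With the pairs they were -2.30 (palbociclib + giredestrant), -1.20 (palbociclib + inavolisib) and -1.38 (giredestrant + inavolisib). In the same order the 24 h values were -0.51, -0.36, -0.19, -0.86, -0.66 and -0.61. None of these medians was tested. With palbociclib + giredestrant, LXN, a carboxypeptidase inhibitor, lay below the sum by a log2 value of -0.89 (SE 0.14, adjusted p = 0.0081), as did the keratin KRT81 (-2.20, SE 0.39). With palbociclib + inavolisib, CAV1, the main caveolar protein, lay below it by -0.83 (SE 0.12, adjusted p = 0.0021), as did the ERBB ligand gene NRG1 (-5.37, SE 0.97). With giredestrant + inavolisib, PPM1E (0.89, SE 0.16), the alanyl-tRNA synthetase AARS (0.81, SE 0.16) and CDC20B (7.74, SE 1.23) lay above it and the keratin KRT19 (-0.59, SE 0.11) below it. KRT81, NRG1 and CDC20B, at 5.05, 1.20 and 1.25 CPM, were named after their values were seen. At an unadjusted p below 0.05 these terms held 578, 490 and 1201 genes, where 705 would be due to chance, and DESeq2 called 0, 1 and 4. Of the 4 for giredestrant + inavolisib only 1 was among the 4 of edgeR. With 1 condition left out the giredestrant + inavolisib count ranged from 0 (such as without inavolisib at 24 h) to 57 (without palbociclib at 96 h).

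The ATF4 and amino acid genes stood above the sum for giredestrant + inavolisib, with a median of 0.66. Of these genes 0 of 25 passed over all genes and 16 did adjusted over the list alone (adjusted p = 7.8e-13, and 0.61 with an estimated correlation). They were lower than in vehicle with each drug and with the pair by similar amounts. At 96 h the medians were -1.06 with giredestrant, -0.74 with inavolisib and -0.68 with both. For PHGDH the levels at 96 h were 127 CPM with vehicle, 20.5 with giredestrant, 20.5 with inavolisib and 15 with both. The p53 targets (median 0.34, 0 of 21 called, 0.61) and luminal markers (-0.24, KRT19 lower and 6 of 15 lower adjusted over the list alone, 0.61) also passed with the preset correlation only, the last value being the adjusted p with an estimated correlation. For palbociclib + giredestrant the preset test passed G1/S genes (0.27, 0.90), ATF4 and amino acid genes (0.30, 0.90), p53 targets (0.12, 0.90) and basal and mesenchymal markers (-0.50, 0.81). For palbociclib + inavolisib it passed ATF4 and amino acid genes (0.24, 0.96) and p53 targets (0.15, 0.96). No gene was called in any of these lists, and each median is followed by the adjusted p with an estimated correlation.

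Adding inavolisib to giredestrant changed 211 genes (125 higher, 86 lower). CAV1 (ENSG00000105974, chromosome 7, 116524785 to 116561184, plus strand) rose by 1.26 (SE 0.12, adjusted p = 6.3e-08), SAT1, a polyamine-degrading enzyme, by 1.03 (SE 0.14) and the RNA gene SNHG12 by 1.23 (SE 0.17), whereas CRABP2 (-0.90, SE 0.10), PHLDA2 (-0.93, SE 0.10) and MT-ND6 (-0.66, SE 0.11) fell. FOXO and PI3K feedback genes rose in 6 of 24 cases (11 adjusted over the list alone, median 0.39, adjusted p = 0.011 with an estimated correlation). Other lists passed with the preset correlation only, the last value being the adjusted p with an estimated correlation. Mitochondrially encoded genes were lower (6 of 13, 12 adjusted over the list alone, median -0.37, 0.75), as were cholesterol and fatty acid synthesis genes (1 of 28, median -0.21, 0.83). MAPK early-response genes were higher (2 of 18, 7 adjusted over the list alone, median 0.36, 0.39), as were p53 targets (2 of 21, median 0.21, 0.83). DESeq2 called 60. Over fits lacking 1 condition each, the count ran from 18 (without giredestrant at 96 h) to 470 (without palbociclib at 96 h).

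Adding palbociclib to inavolisib lowered CKS1B (-0.82, SE 0.12, adjusted p = 0.0021), HIST2H2AC (-0.88, SE 0.14, adjusted p = 0.0046) and the replication helicase gene MCM5 (-1.17, SE 0.22, adjusted p = 0.044), the 3 genes called. G1/S genes had a median of -0.95 with 1 of 30 lower, 15 adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). G2/M genes had a median of -0.80 with 0 of 30 called and 15 lower adjusted over the list alone (adjusted p = 0.44 with an estimated correlation). Estrogen-repressed genes had a median of 0.27 with 0 of 10 called (adjusted p = 0.39 with an estimated correlation). Adding palbociclib to giredestrant raised ANGPTL4 (1.21, SE 0.21, adjusted p = 0.043), a lipase inhibitor and the 1 gene called. G2/M genes had a median of -0.56 with 0 of 30 called and 1 lower adjusted over the list alone (adjusted p = 0.67 with an estimated correlation). G1/S genes had a median of -0.39 with 0 of 30 called (adjusted p = 0.85 with an estimated correlation). ANGPTL4 and MCM5 were named after their values were seen. DESeq2 called 0 for both of these additions of palbociclib, and without palbociclib at 96 h edgeR called 157 on top of inavolisib and 26 on top of giredestrant.

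All 3 drugs against vehicle changed 2977 genes (1384 higher, 1593 lower). Of 31 estrogen-induced genes 29 fell (29 adjusted over the list alone, median -1.50, adjusted p = 0.014 with an estimated correlation). Of 10 estrogen-repressed genes 7 rose (7 adjusted over the list alone, median 1.08, 0.040). FOXO and PI3K feedback genes rose in 20 of 24 cases and fell in 2 (21 and 2 adjusted over the list alone, median 0.81, 0.014), with GABARAPL1, an autophagy protein, at 2.83 (SE 0.53). Of 30 G1/S genes 22 fell (26 adjusted over the list alone, median -1.72, 0.31), such as CLSPN (-3.94, SE 0.63). Of 30 G2/M genes 22 fell (30 adjusted over the list alone, median -1.80, 0.31), such as BUB1B of the spindle checkpoint (-2.68, SE 0.34). All 13 mitochondrially encoded genes fell (median -0.62, 0.31). Further lists passed with the preset correlation only. Higher were lysosome and autophagy genes (9 of 18 higher, 1 lower, the same adjusted over the list alone, median 0.33, 0.31) and interferon and antigen presentation genes (9 of 24 higher, 11 adjusted over the list alone, median 0.46, 0.40). So were p53 targets (6 of 21 higher, 1 lower, 8 and 1 adjusted over the list alone, median 0.30, 0.42) and MAPK early-response genes (6 of 18 higher, 2 lower, 6 and 4 adjusted over the list alone, median 0.50, 0.36). Lower were cholesterol and fatty acid synthesis genes (10 of 28 lower, 1 higher, 14 and 1 adjusted over the list alone, median -0.38, 0.33) and ATF4 and amino acid genes (10 of 25 lower, 2 higher, 15 and 2 adjusted over the list alone, median -0.70, 0.42). MYC and ribosome biogenesis genes were lower too (11 of 22, 12 adjusted over the list alone, median -0.42, 0.065). In this paragraph the last value for each list is its adjusted p with an estimated correlation. The genes with the smallest p were BCAS4 (1.38, SE 0.09), HILPDA, a lipid droplet protein (1.55, SE 0.10), and YPEL3 (1.38, SE 0.10) among the higher. Among the lower they were GFRA1, a GDNF receptor (-2.22, SE 0.11), RERG, a RAS-like growth inhibitor (-2.49, SE 0.12), and PKIB, a kinase inhibitor (-2.15, SE 0.12). DESeq2 called 1495. The count was 1870 without vehicle at 24 h and 1952 without all 3 drugs at 24 h.

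**Figure D4:**
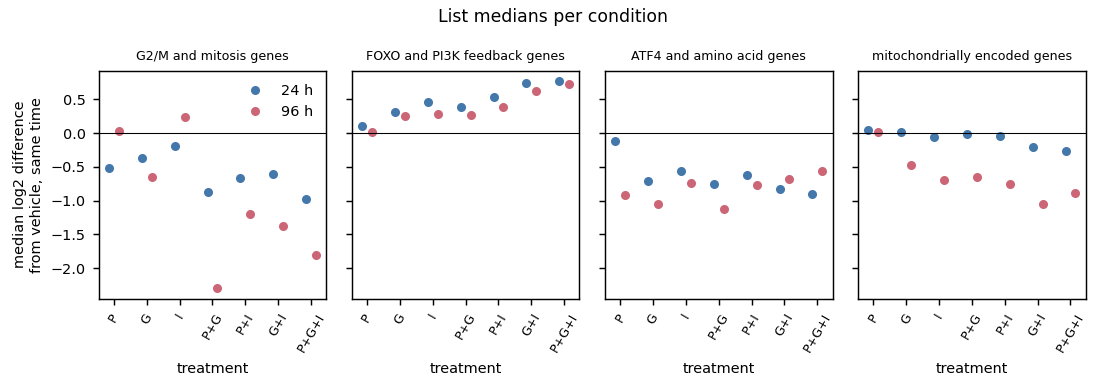
Median log2 difference from vehicle at the same time (vertical axis) of 4 gene lists in the 7 drug treatments (horizontal axis) at 24 h (blue) and 96 h (red), 1 value per condition. For G2/M genes it was -2.30 with palbociclib + giredestrant and 0.03 with palbociclib alone at 96 h.

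The last comparison asked which drug effects differed between 96 and 24 h. For giredestrant 179 genes did (116 higher at 96 h, 63 lower; 156 and 29 without scaling factors). LXN (ENSG00000079257, chromosome 3, 158645822 to 158672693, minus strand) had the smallest p, with a difference of 1.49 (SE 0.14, adjusted p = 1.6e-07): giredestrant alone gave 44.4 CPM at 24 h and 222 CPM at 96 h, against 31.4 and 40.9 CPM in vehicle. DTNA (0.96, SE 0.11), of the dystrophin complex, and the secreted chaperone CLU (1.06, SE 0.13) were also higher at 96 h. Lower at 96 h were CLSTN2 (-0.82, SE 0.14), GFRA1 (-0.71, SE 0.12) and SLC4A10 (-1.47, SE 0.26), a bicarbonate transporter. G2/M genes were lower at 96 h in 3 of 30 cases (14 adjusted over the list alone, median -1.04, adjusted p = 0.49 with an estimated correlation) and MYC was higher (1.09, SE 0.24, adjusted p = 0.017). Mitochondrially encoded genes were lower in 2 of 13 cases, MT-CO1 (-0.49, SE 0.11) and MT-CO2 (-0.47, SE 0.11), and 9 adjusted over the list alone (median -0.35, 0.49). Further lists passed with the preset correlation only, the last value being the adjusted p with an estimated correlation. Higher at 96 h were interferon genes (median 0.48, 1 of 24 higher, 5 higher and 1 lower adjusted over the list alone, 0.49) and MAPK genes (median 0.26, 2 of 18 higher, 0.49). So were ATF4 and amino acid genes (median 0.20, 0 of 25 called, 2 higher adjusted over the list alone, 0.73) and MYC and ribosome biogenesis genes (median 0.17, 1 of 22 higher, 0.49). Lower were G1/S genes (median -0.27, 0 of 30 called, 0.73). These terms are fitted over all drug backgrounds, and giredestrant alone went the other way for 2 lists. Against vehicle, its ATF4 and amino acid median was -0.71 at 24 h and -1.06 at 96 h, and its G1/S median -0.96 at 24 h and -0.31 at 96 h. DESeq2 called 55. The count ranged, with any 1 condition omitted, from 65 (without palbociclib + giredestrant at 24 h) to 496 (without vehicle at 96 h), with 322 without palbociclib at 96 h.

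For inavolisib 44 genes differed between times (20 higher at 96 h, 24 lower; 10 and 16 without scaling factors). CAV1 (0.97, SE 0.12, adjusted p = 5.4e-05) went from 58.5 CPM in vehicle to 109 with inavolisib at 24 h and from 82.0 to 307 CPM at 96 h, while the clone-named transcript AC021148.2 (1.20, SE 0.15) and the G protein subunit GNA14 (0.96, SE 0.13) were higher as well. MT-ND6, a subunit of respiratory complex I (ENSG00000198695, mitochondrial genome, 14149 to 14673, minus strand), was lower (-0.74, SE 0.12, adjusted p = 0.0026), with AC245297.3 (-1.90, SE 0.30) and CCDC83 (-1.50, SE 0.26). Of 13 mitochondrially encoded genes 5 were lower, 13 adjusted over the list alone (median -0.48, adjusted p = 0.41 with an estimated correlation). AREG was lower at 96 h too (-1.32, SE 0.23, adjusted p = 0.042). Further lists passed with the preset correlation only, with 0 genes called over all genes unless stated and the last value being the adjusted p with an estimated correlation. All had a positive term. They were ATF4 and amino acid genes (median 0.40, 2 adjusted over the list alone, 0.51), MAPK genes (median 0.36, 3 adjusted over the list alone, 0.41) and interferon genes (median 0.21, 3 adjusted over the list alone, 0.51). Estrogen-induced genes (median 0.12, 1 of 31 higher and 1 lower, 2 and 2 adjusted over the list alone, 0.51) and cholesterol and fatty acid synthesis genes (median 0.18, 0.51) passed too. Heat shock genes (median 0.11, 0.51) and basal and mesenchymal markers (median 0.38, 0.41) were the last. Inavolisib alone against vehicle went the other way for ATF4 and amino acid genes (-0.56 at 24 h, -0.74 at 96 h), and hardly moved for estrogen-induced (0.00 and -0.01) and heat shock genes (-0.02 and -0.02). DESeq2 called 13. Leaving out 1 condition at a time moved the count from 10 (without inavolisib at 24 h) to 272 (without vehicle at 96 h), with 150 without giredestrant + inavolisib at 24 h.

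For palbociclib only the chemokine gene CCL5 differed (5.79, SE 0.81, adjusted p = 0.0042; 3.79 CPM, named after its value was seen). In edgeR 634 genes had an unadjusted p below 0.05 and DESeq2 called 0. The preset test passed G2/M genes (-0.30, 0.88), estrogen-induced genes (0.07, 0.88) and MAPK genes (0.30, 2 of 18 higher adjusted over the list alone, 0.88) for palbociclib by time, with 0 genes called over all genes and each median again followed by the adjusted p with an estimated correlation. Palbociclib alone against vehicle went the other way for G2/M genes (-0.51 at 24 h, 0.03 at 96 h) and for estrogen-induced genes (-0.02 and -0.13). Other lists had a preset adjusted p of 0.05 or more under the same comparison. The lists of colon, fibroblast and blood cell markers each had 1 gene with enough counts to be tested and are not read as lists.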

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

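The counts of changed genes of 13 comparisons were first set against other splits of the 16 conditions, in which the labels of a drug (or of time) were swapped within some of the 8 pairs, a test fixed before the data for the interactions and chosen after the results were seen for the rest. For giredestrant 1 of 40 splits, the real one, had as many as 2042 genes (highest other 1325), for inavolisib 1 of 40 (139, highest other 74), and for time 1 of 40 (18, highest other 3), so chance is a poor account of these. For palbociclib 5 of 40 splits had as many as its 12 genes (highest other 18), for palbociclib added to giredestrant 9 of 40 (1, highest other 7), for palbociclib added to inavolisib 8 of 40 (3, highest other 201) and for inavolisib added to giredestrant 2 of 40 (211, highest other 310), so chance remains open there. Interactions were tested in a simpler model with a term per pair, in which the 8 pairs were split into 4 and 4 in every way. There giredestrant by time had 121 genes and 1 of 35 splits reached that (highest other 10), inavolisib by time 16 genes and 2 of 35 (highest other 38), and palbociclib by time 3 genes and 4 of 35 (highest other 84). The 3 drug pairs had 0 genes in that model, which all 35 of 35 splits reached, with 121, 38 and 38 as the highest other counts; the split with 121 is the one by time. The count for all 3 drugs against vehicle and the list results were not set against such splits.

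All further tests here were chosen after the results were seen. At 96 h palbociclib alone was not below vehicle in cycling cells (15.6% against 13.3%) nor in cell cycle genes. A full mix-up with cells of that vehicle culture fits poorly, because the ATF4 and amino acid genes had a median of -0.91 against it (quartiles -1.05 to -0.47). This was the value that lay far from its 7 sister pairs, and the list was chosen after it had been seen. It cannot decide on a partial mix-up or on another vehicle well, since the number of wells is not stated. Cells with a high mitochondrial share fit poorly too, because the difference in cycling cells was 3.04 percentage points in cells with at most 10% mitochondrial UMIs. A culture without working palbociclib could not be told apart from a lapsed effect: the 54 genes that rose in the other 3 palbociclib pairs had a median of 0.13 here (quartiles -0.09 to 0.33) against 0.47 there. The vehicle culture at 96 h may also be at fault: inavolisib alone lay above it in cycling cells too (16.8%). Leaving that vehicle culture out gave 171 palbociclib genes, against 190 without palbociclib at 96 h. It is unlikely to be the whole account. Palbociclib alone went from 6.82% cycling cells at 24 h to 15.6% at 96 h, against 14.7% in vehicle at 24 h, and these values do not involve it.

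Mitochondrially encoded genes were lower with inavolisib at 96 h than at 24 h by the preset test (median -0.48), but not with an estimated correlation (adjusted p = 0.41), and chance remains open for the count of this term (2 of 35 splits). Damaged or shallow cells are a poor account, as the median was -0.39 in cells with at least 2000 UMIs and at most 15% mitochondrial UMIs (quartiles -0.47 to -0.30). Scaling between conditions is a poor account as well, as the median was -0.53 without scaling factors (quartiles -0.59 to -0.43). Neither test tells fewer mitochondria from lower transcription.

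ATF4 and amino acid genes were lower with each single drug by the preset test and hardly lower still with 2. None of this held with an estimated correlation (adjusted p = 0.49 for giredestrant, 0.49 for palbociclib and 0.28 for inavolisib), and with palbociclib at 24 h the median was only -0.12. High vehicle values alone do not account for this at 24 h, where the smaller of the moves with giredestrant and inavolisib against palbociclib alone was -0.54. At 96 h that move was 0.21, so there a high vehicle culture remains a sufficient account. Counts at their floor are a poor account, as 4 of 25 genes had 3 or fewer UMIs in their lowest single-drug condition.

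Other values stood out. Of 29 groups of 8 values 2 held an outlier, where chance gives about 1 in 20; the second was the mean mitochondrial share at 24 h with all 3 drugs, 6.45%. Effects differed between times for 179 genes with giredestrant, 44 with inavolisib and 1 with palbociclib. For giredestrant those with the smallest p in each direction, among genes of at least 10 CPM, were LXN (1.49), DTNA (0.96) and CLU (1.06), higher at 96 h, and CLSTN2 (-0.82), GFRA1 (-0.71) and SLC4A10 (-1.47), lower. For inavolisib they were AC021148.2 (1.20), CAV1 (0.97), GNA14 (0.96), MT-ND6 (-0.74), AC245297.3 (-1.90) and CCDC83 (-1.50). The cells without a condition held 110700041 UMIs, more than all cells with one.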

How the results depend on the processing

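No called result of a named gene changed sign under DESeq2 or without scaling factors. Nor did any in cells with at least 2000 UMIs and at most 15% mitochondrial UMIs. Results that were not called were counted as unchanged even if their sign flipped, as long as they stayed uncalled or flipped. Under the other alternatives only counts of genes were compared. Among results for named genes 39 were no longer called under DESeq2 (250 unchanged), 24 without scaling factors (266 unchanged) and 5 in those cells (280 unchanged), where a few genes were not tested. Counts of changed genes moved by more than 1.5-fold as follows, the value of the chosen analysis being in the results above. DESeq2 gave 864 genes for giredestrant, 0 for palbociclib, 48 for inavolisib, 7 for time, 0 for palbociclib + giredestrant beyond additive, 1 for palbociclib + inavolisib beyond additive, 55 for giredestrant by time, 0 for palbociclib by time, 13 for inavolisib by time, 0 for palbociclib added to giredestrant, 60 for inavolisib added to giredestrant, 0 for palbociclib added to inavolisib and 1495 for all 3 drugs. With no filter on low counts these were 147 for palbociclib, 247 for inavolisib, 104 for time, 11, 8 and 104 for the pairs (palbociclib + giredestrant, palbociclib + inavolisib, giredestrant + inavolisib), 407 for giredestrant by time, 19 for palbociclib by time, 175 for inavolisib by time, 39 for palbociclib added to giredestrant, 354 for inavolisib added to giredestrant and 176 for palbociclib added to inavolisib. Without interaction terms there were 3642 for giredestrant, 31 for palbociclib, 944 for inavolisib and 1281 for time. Palbociclib gave 23 genes in cells with at least 2000 UMIs and at most 15% mitochondrial UMIs and 32 with 430 cells per condition. A term for all 3 drugs gave 1 for palbociclib + giredestrant, 1 for giredestrant + inavolisib and 69 for palbociclib added to inavolisib. Without scaling factors there were 0 for palbociclib, 0 for palbociclib + giredestrant, 1 for palbociclib + inavolisib, 26 for inavolisib by time and 0 for palbociclib added to giredestrant.

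For the share of cycling cells (percentage points) the sign of no difference changed, but calls did. Without thinning palbociclib (-4.04, adjusted p = 0.141) was no longer called and inavolisib was (-5.36, adjusted p = 0.0352). No longer called were also, at 2000 UMIs, giredestrant (-3.85, adjusted p = 0.0859) and palbociclib (-4.37, adjusted p = 0.0859), with phases from list scores giredestrant (-9.07, adjusted p = 0.141) and palbociclib (-5.55, adjusted p = 0.141), and in cells with at most 10% mitochondrial UMIs giredestrant (-3.87, adjusted p = 0.0586) and palbociclib (-3.51, adjusted p = 0.0586). Of 220 list tests over the planned contrasts 60 passed with the preset correlation and 2 with an estimated one.

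Leaving out each condition in turn gave ranges of 1135 to 2629 for giredestrant, 2 to 190 for palbociclib, 39 to 342 for inavolisib, 5 to 265 for time, 0 to 5, 0 to 3 and 0 to 57 for the pairs in the order above, 65 to 496 for giredestrant by time, 0 to 8 for palbociclib by time, 10 to 272 for inavolisib by time, 0 to 26 for palbociclib added to giredestrant, 18 to 470 for inavolisib added to giredestrant, 0 to 173 for palbociclib added to inavolisib and 1870 to 3345 for all 3 drugs; the highest values came mostly without vehicle or palbociclib at 96 h. Leave-outs, missing scaling factors, the limit of 10% mitochondrial UMIs and the sums of terms were chosen after seeing the data. Fits without each library and sums per condition and library were planned but not run, since no cell could be assigned to a library.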

Other observations

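Interferon and antigen presentation genes had positive medians against vehicle at 96 h in all treatments except palbociclib alone (-0.03). The median was 0.62 with giredestrant (22 of 24 genes higher), 0.65 with palbociclib + giredestrant, 0.49 with giredestrant + inavolisib and 0.69 with all 3 drugs, and, without giredestrant, 0.31 with inavolisib (21 of 24 higher) and 0.26 with palbociclib + inavolisib (19 of 24 higher). With all 3 drugs IFIT3 rose by 2.88 (SE 0.78, adjusted p = 0.018) and, among p53 targets, BTG2, an antiproliferative gene, by 2.08 (SE 0.23). UHRF1, which maintains DNA methylation, changed by -4.94 (SE 0.76), and CXCL12, a chemokine induced by estrogen, by -2.91 (SE 0.32). The medians are single values per condition and were not tested alone. All are set against the same vehicle culture at 96 h, so a low vehicle value would raise them together.

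The 14808 cells without a condition lay mostly within the range of the 16 conditions in expression. Their median depth was 6553 UMIs (3993 to 6727.5 in the conditions) and their median mitochondrial share 3.62% (2.46% to 4.92% in the conditions). Of these cells 92.6% passed the limits of at least 2000 UMIs and at most 15% mitochondrial UMIs, against 75.1% to 90.2% in the conditions. Cycling cells made up 12.7% (95% interval 12.1 to 13.2). Of 8455 genes at 10 CPM or more, 8321 lay within the range of the 16 conditions, 40 above and 94 below it, and 2 lay outside it by more than 1.5-fold: PHKG1, a phosphorylase kinase subunit, at 16.9 CPM against at most 9.93, and LRRC75A at 83.1 CPM against at most 53.3. The range spans all drug treatments, so a large pooled sum tends to fall inside it and a moderate difference would not show. Whether these cells include the ESR1-mutant line is not stated, and the available labels do not settle it.

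With each drug alone at 96 h, most unfolded protein response genes and p53 targets lay below vehicle. Unfolded protein response genes did so in 13 of 14 cases with palbociclib (median -0.23), 12 of 14 with giredestrant (median -0.17) and 12 of 14 with inavolisib (median -0.21). For p53 targets it was 17 of 21 with palbociclib (median -0.37), 15 of 21 with giredestrant (median -0.21) and 17 of 21 with inavolisib (median -0.31). In the combinations at 96 h the p53 median was positive with giredestrant + inavolisib (0.16) and all 3 drugs (0.46). It was negative with palbociclib + giredestrant (-0.15) and palbociclib + inavolisib (-0.19). The single drugs are all set against the same vehicle culture here, so a high vehicle value would give the same picture for them.

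The phase of a cell by list scores was a weak call, since 57.2% of cells lay within 0.05 of a boundary between phases.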
